A study of Homo sapiens with 46 samples.

How the data were processed

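Total RNA of cultured cells of 23 human breast cancer lines was isolated with a silica column kit and turned into biotin-labelled cRNA, per the labels' protocols. Each line was hybridised to 1 Affymetrix U133A array and 1 U133B array. Per the submitters' processing notes, the values were made with MAS5, the Affymetrix algorithm that compares perfect match with mismatch probes. Its version and scaling target are not given in the sources used here. The deposited values were signal intensities on a linear scale, with no negative or missing value. The mean without the outer 2% at each end was about 1500 on every array of both designs (1499.63 to 1499.71 on U133A and 1499.87 to 1499.90 on U133B), so arrays of a design were compared as deposited. The median signal ran from 401 to 569 on U133A and from 626 to 969 on U133B. Detection calls were not used here. MAS5 signals of low probe sets are noisy, which is why a pseudocount and a filter were used.

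Signals were turned into log2(signal + pseudocount), with a pseudocount of 0.25 times the design's median signal (129 on U133A and 184 on U133B), so a fold change is on that scale and understates the change of low genes. Levels were never compared between designs, except over the probe sets carried by both. Probe sets were kept for tests when they reached the array median in at least 3 of 21 lines, which left 30619 of 44692, the 68 control probe sets of each design and the U133B copies of the 100 shared probe sets having been left out. Line labels came from sample titles, and each line was a group of 1, since the labels give no groups of lines. MCF7/Her2, named as a derivative of MCF7, and AU-565, a sister line of SK-BR-3 in cell bank records, were left out of tests over lines. The 21 lines left were treated as independent samples. H3396 and MCF7, both among them, lay close together (r = 0.379 over centred probe sets), and whether they are related was not tested. ERBB2 did not follow the label of the line labelled MCF7/Her2, which is therefore always written so in results.

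Genes were named through the platform annotation tables and updated by gene ID to the RefSeq table of assembly GRCh38.p14, used for names alone. On U133A 19071 probe sets had 1 gene, 1043 had several and 2169 were not listed, and 19059 of the first were matched by gene ID. On U133B these numbers were 15432, 554, 6659 and 15407. No gene was named from a probe set with several. For a gene of a list, the brightest probe set annotated to that gene alone was taken, which gave 259 of 278 genes; AR, KRT6B, KRT17, TP63, LAMC2, FOXC1, SERPINE1, HCK, DDR1, FLNA, VMP1, PTRH2, STAT1, TP53, PTEN, DCT, CD19, CD68 and CA9 had none. No coordinates were used.

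Before the data were examined, 25 gene lists were fixed, together with the tests, the alternatives and the rule for named genes. The sources used name neither the drug nor markers of response, so the dasatinib and published marker lists came from general knowledge. The lists were the oestrogen receptor programme, luminal identity, epithelial junction, basal keratin and basal epithelial, mesenchymal, published candidate markers, dasatinib target kinases, focal adhesion, receptor tyrosine kinases, the 17q12 neighbours of ERBB2, the 11q13, 8p12, 17q23 and 20q13 amplicons, proliferation, interferon response, MHC class II, tumour suppressors, hypoxia and unfolded protein response. Markers of other cell types were melanocyte, leukocyte, endothelial, fibroblast stroma and neuroendocrine. In the tests with EPHA2, ESR1 and ERBB2 the endothelial list had no set test. Named genes were up to 12 of each direction by smallest p in each scan and up to 10 of each direction by size in each pair of lines. Up to 2 per line were named by the gap between 1 line and the next unrelated line. Members of the lists that passed were named too.

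Genes that vary with EPHA2, ESR1 or ERBB2 were found with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend) as the slope of log2 signal on the log2 signal of the index gene, per design, with Benjamini-Hochberg adjustment over both designs. Where the index gene's widest gap, with at least 3 lines on each side, exceeded the 95th percentile of normal samples, the cluster was a term in the fit, which held for ERBB2 alone. Lists were tested with camera, with the preset and with an estimated correlation, both adjusted over the lists of an index gene. Within a list, a second adjustment ran over the list alone. In these set tests the median slope, the mean slope and the test's direction differed in sign for receptor tyrosine kinases, tumour suppressors and the unfolded protein response with EPHA2, for receptor tyrosine kinases, melanocyte and leukocyte markers with ESR1, and for tumour suppressors, leukocyte markers and 20q13 with ERBB2, none of which was called.

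List scores were related by Pearson's r and Spearman's rho with two-sided permutation tests (100000 resamples, exact below 10 lines), adjusted over 28 relations. Where a score fell into clusters, r was taken within clusters of at least 6 lines, and genes held by both lists were left out of both. How far a list's genes moved together was their mean pairwise r against 10000 random lists of matched signal. For pairs of lines, with no replicates, differences of at least 4-fold were counted among probe sets at or above the array median in the brighter line, and list medians were set as percentiles of 10000 random lists of matched signal, with no test. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.

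The steps were tested on simulated data. With 100 probe sets changed at each size among those tested (30618, 30613 and 30616), slopes of 1 residual SD per SD of the index were recovered for 66% with EPHA2, 58% with ESR1 and 58% with ERBB2, and slopes of 2 SD for 100% with each. False calls made up 5.14%, 5.95% and 5.95% of the calls. The noise was drawn independently for each probe set, whereas real probe sets vary together, so these shares need not hold for the real scans. Of 200 simulated relations over 21 lines, 7% with a true r of 0 and 97% with a true r of 0.7 had p under 0.05.

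Alternatives were pseudocounts of 0.05 and 1 times the median, quantile normalization, no filter and a 75th percentile filter, all 23 lines, the lines without MDA-MB-435S, which cell banks trace to a melanoma line, each line left out in turn, the mean of a gene's probe sets, and the other choice of cluster term. After the data were seen, U133A arrays alone, the lines without MDA-MB-453, BT-474 and ZR-75-1, a luminal identity term and a term for the junction clusters were added. Drug responses, copy number and coordinates were not analysed here.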

Results

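The data collected were RNA levels of 23 cultured human breast cancer cell lines, each measured on 1 Affymetrix U133A array and 1 Affymetrix U133B array, 46 arrays in all. The U133A design carried 22283 probe sets and the U133B design 22645. According to the design text, the baseline profiles were made to find expression signatures that go with sensitivity to a drug in culture. The sources used do not name the drug, and its responses were not used here. Among the lines, the line labelled MCF7/Her2 is named as a derivative of MCF7, a line that expresses the oestrogen receptor. AU-565 is a sister line of SK-BR-3, a line with amplified ERBB2. Tests over lines used the 21 lines left without MCF7/Her2 and AU-565. No line was measured more than once on a design, so the data held no replicates. The number of arrays limits the precision.

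The levels of 3 receptor genes set the lines apart. ERBB2, the HER2 receptor kinase, had a median signal of 2326 over the 21 lines and 71366 in HCC1954, 70452 in SK-BR-3, 63186 in HCC1419, 61360 in BT-474 and 56325 in ZR-75-30. AU-565 read 60815, and the next line, MDA-MB-453, read 15798. ESR1, the oestrogen receptor, read 18119 in H3396, 17279 in MCF7, 13495 in the line labelled MCF7/Her2 and 8571 in HCC1428, against a median of 687. EPHA2, an ephrin receptor kinase that dasatinib inhibits, ranged from 202 in MDA-MB-453 to 6712 in MDA-MB-231, with a median of 1451. The gap in ERBB2 between the 5 highest and the other 16 of the 21 lines was 0.293 of the range, above the limit of 0.220 that normal samples of that size allow. EPHA2 (0.135) and ESR1 (0.185) lay below that limit.

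**Figure D1:**
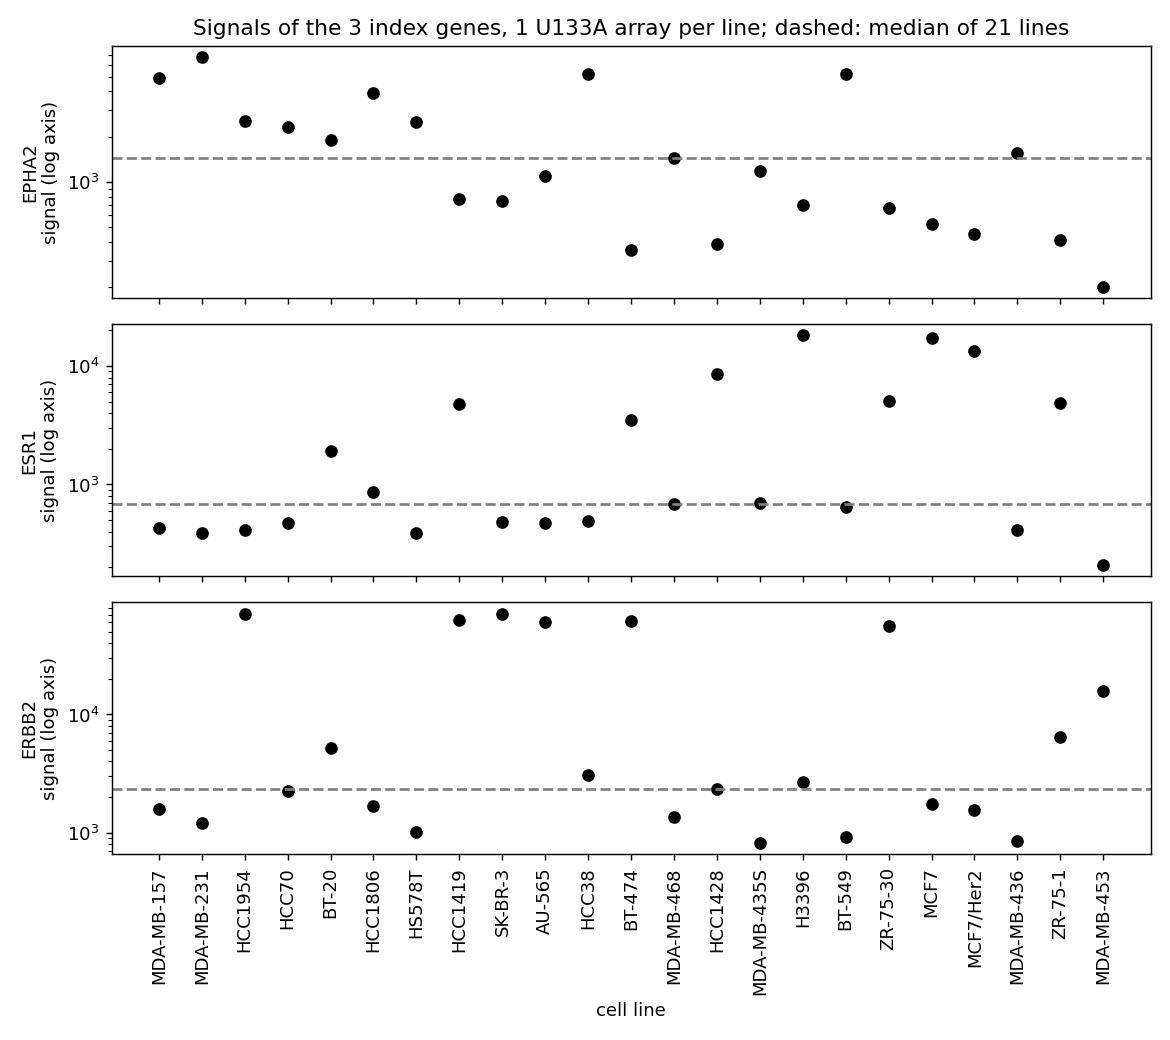
Signals of EPHA2, ESR1 and ERBB2 (log axes) in the 23 lines, 1 point per line, with the median of 21 lines dashed. ERBB2 was at or above 56325 in HCC1954, SK-BR-3, HCC1419, BT-474, AU-565 and ZR-75-30, and at or below 15798 in all others.

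Gene lists fixed before the data were examined followed known divisions of breast cancer cells. A list score is the mean of its members' values, each in SD over the 21 lines. Mesenchymal genes, such as the collagens and vimentin, scored highest in HS578T (2.17), BT-549 (1.51) and MDA-MB-157 (1.28). VIM read 92722 in MDA-MB-157 and 69066 in HS578T, against a median of 2468. COL1A2, a fibrillar collagen chain, read 63372 in HS578T and 19649 in BT-549, with 768 in MDA-MB-157 as the next. Epithelial junction genes scored below the gap in 6 lines, MDA-MB-435S (−1.62), HS578T (−1.51), MDA-MB-436 (−1.39), BT-549 (−1.37), MDA-MB-157 (−1.18) and MDA-MB-231 (−1.03), and between 0.128 and 0.803 in the other 15. Basal keratin and basal epithelial genes formed a higher group of 6 lines led by HCC70 (1.57), MDA-MB-468 (1.17) and HCC38 (1.13). KRT5, a basal keratin, read 48317 in HCC70 and 34333 in HCC1806, and at most 1079 in the lines outside this group. Luminal identity scores were highest in ZR-75-30 (1.26) and HCC1419 (1.24) and lowest in MDA-MB-436 (−1.18).

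**Figure D2:**
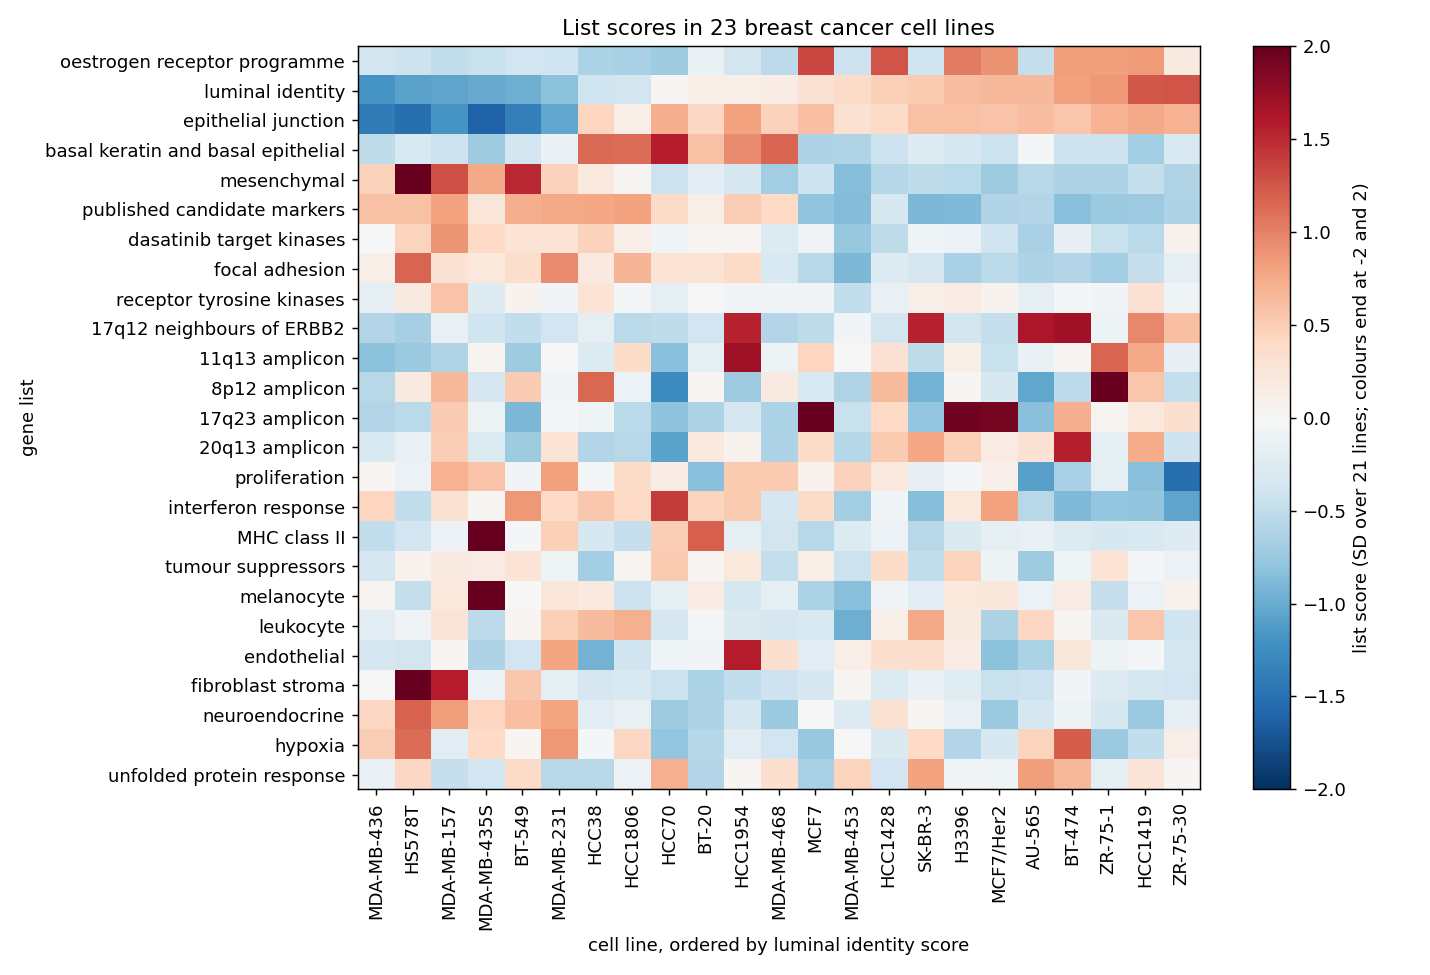
Scores of 25 gene lists (rows, in SD over 21 lines, colours ending at −2 and 2) in the 23 lines (columns, ordered by luminal identity score). The columns on the left, from MDA-MB-436 (−1.18), combined low luminal identity and epithelial junction scores with high mesenchymal scores, up to 2.17 in HS578T.

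Genes that lie together on chromosome arms often amplified in breast cancer stood out in single lines. The 17q12 list, which holds ERBB2 and 11 neighbours, so that it follows ERBB2 in part by its make-up, scored 1.68 in BT-474, 1.54 in HCC1954, 1.53 in SK-BR-3, 0.955 in HCC1419 and 0.594 in ZR-75-30, and at most −0.0520 in the other 16 of the 21 lines. GRB7, an adaptor protein next to ERBB2, read 44482 in HCC1954 and 1258 in the median line. The 17q23 list scored 2.26 in MCF7 and 1.95 in H3396. Its member BCAS3 read 28000 in MCF7, 27938 in the line labelled MCF7/Her2 and 10257 in H3396, and at most 1679 in every other line. The 8p12 list scored 1.98 in ZR-75-1 and 1.15 in HCC38, and the 11q13 list 1.69 in HCC1954 and 1.17 in ZR-75-1. CCND1, the cyclin of 11q13, read 23533 in HCC1954 and 3886 in the median line. The 20q13 list scored 1.55 in BT-474. Copy number was not measured. The U133B arrays of MDA-MB-453, BT-474 and ZR-75-1 deviated from their U133A arrays, so values of these lines on U133B carry a larger error.

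Members of most lists rose and fell together over the lines. The mean pairwise r between members was 0.666 for mesenchymal genes, 0.657 for 17q23, 0.608 for MHC class II genes, 0.585 for luminal identity, 0.554 for fibroblast stroma and 0.506 for 8p12. It was 0.404 for the interferon response, 0.399 for melanocyte markers, 0.312 for 20q13, 0.306 for 11q13, 0.289 for proliferation, 0.278 for hypoxia and 0.261 for focal adhesion. In a one-sided permutation test over 21 lines against 10000 random lists of matched signal, each of these had p = 0.0001, the smallest the draws can give (adjusted p = 0.000242), except 11q13 (p = 0.0008, adjusted p = 0.00166). The family held 29 such tests. Dasatinib target kinases, which include the SRC family, had a mean r of only 0.0915 (adjusted p = 0.00445).

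Some lists split the lines into clusters, and r was then taken within a cluster. The 17q12 list had a mean r of 0.129 in the 16 lines below its gap (adjusted p = 0.00888). The oestrogen receptor programme had 0.0848 in its 15 lower lines (adjusted p = 0.0179) and 0.0663 in its 6 higher lines (adjusted p = 0.120). Epithelial junction genes had 0.211 in the 6 lower lines (adjusted p = 0.00166) and 0.0973 in the 15 higher lines (adjusted p = 0.0125). The published candidate markers EPHA2, CAV1, CAV2, ANXA1, CAVIN1 and IGFBP2 had 0.0211 in their 9 lower lines (adjusted p = 0.414) and 0.167 in the 12 higher ones (adjusted p = 0.0568). Basal genes had −0.00217 in 15 lines and 0.0459 in 6 (adjusted p = 0.528 and 0.217). Without ZR-75-30 the oestrogen receptor programme's lower lines gave 0.0131, no longer past the threshold, and without HCC1806 the junction list's higher lines gave 0.0561, likewise.

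Lists that did not pass this test were receptor tyrosine kinases (mean r −0.00387, adjusted p = 0.584), tumour suppressors (0.00813, adjusted p = 0.442), leukocyte markers (0.0412, adjusted p = 0.325) and endothelial markers (0.0961, adjusted p = 0.179). Neuroendocrine markers (0.157, adjusted p = 0.0551) and the unfolded protein response (0.114, adjusted p = 0.0520) lay just above the threshold. They passed it without BT-549 (0.198) and without H3396 (0.132), respectively.

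Luminal identity and mesenchymal scores opposed each other. Over the 21 lines Pearson's r was −0.837 and Spearman's rho −0.844, with a permutation p of 1e-05 for r, the smallest that 100000 resamples can give, and 3e-05 for rho (adjusted p = 0.00028 and 0.00084, two-sided). Without MDA-MB-436 and HS578T, the lines farthest from the luminal median, r was −0.859. The family held 28 relations over 16 pairs of lists, and r passed an adjusted p of 0.05 in 3 of them.

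**Figure D3:**
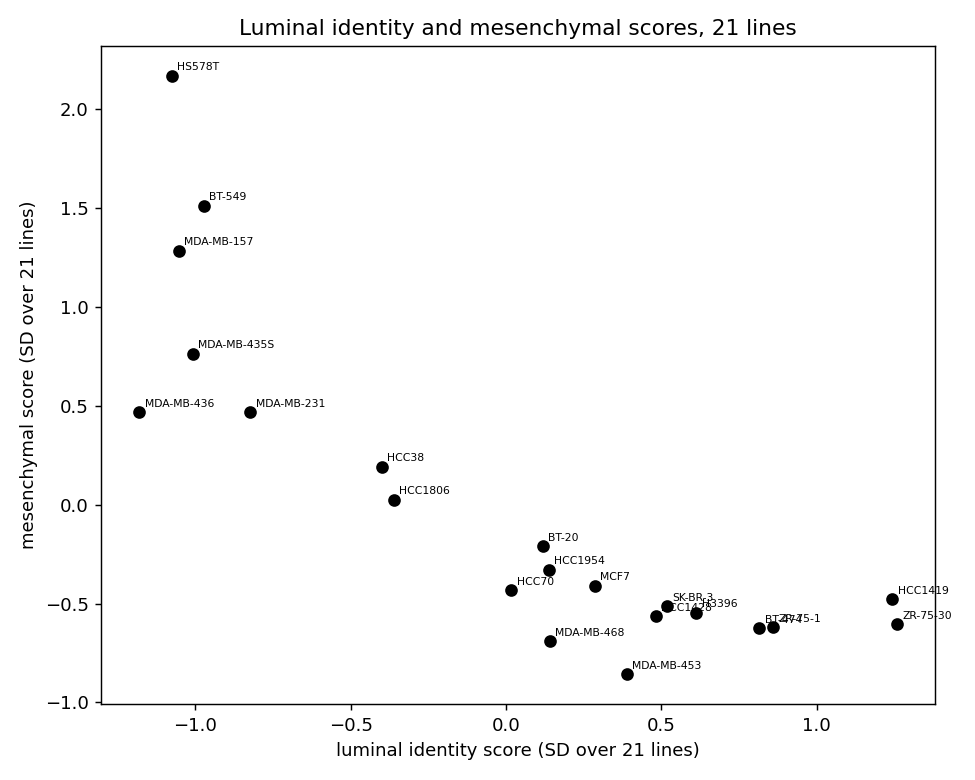
Mesenchymal score against luminal identity score (both in SD over 21 lines), 1 point per line. The points ran from HS578T (2.17 on the vertical axis) to the luminal lines ZR-75-30 and HCC1419 (1.26 and 1.24 on the horizontal axis), with r = −0.837.

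Proliferation genes, such as MKI67 and TOP2A, were lower in lines with higher luminal identity scores (r = −0.592, permutation p = 0.00393, adjusted p = 0.0467, n = 21). Spearman's rho was −0.503 (permutation p = 0.0214, adjusted p = 0.200). Without ZR-75-30 and BT-20 r was −0.533, and without ZR-75-30 alone, the line with the lowest proliferation score (−1.51), it was −0.499 and no longer past the threshold. Within the 15 lines of lower oestrogen receptor programme, proliferation had r = −0.732 with that programme (permutation p = 0.0050, adjusted p = 0.0467) and rho = −0.457 (permutation p = 0.0886, adjusted p = 0.480). That relation rested on ZR-75-30 and BT-20, since r was 0.0302 without them. Without ZR-75-30 alone it was −0.407, no longer past the threshold.

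Interferon response genes were lower in lines of higher luminal identity by rho (−0.639, permutation p = 0.00215, adjusted p = 0.0301, n = 21). Pearson's r was −0.567 (permutation p = 0.00778, adjusted p = 0.0545), and −0.590 without ZR-75-30 and HCC70. Without HS578T r was −0.664 and passed the threshold. The interferon response had r = 0.222 with MHC class II genes (rho 0.297, permutation p = 0.354 and 0.192, adjusted p = 0.551 and 0.483), and 0.169 without ZR-75-30 and HCC70. Of the other 23 relations none passed an adjusted p of 0.05, by r or by rho.

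Which genes vary with EPHA2 over the 21 lines was asked because EPHA2 is a target of the kinase inhibitor dasatinib and a published candidate marker of response to it, a choice made from general knowledge. CAVIN1, a caveolar coat protein, had the smallest p of all genes. It rose by 1.76 ± 0.172 (SE) on the log2 scale per log2 unit of EPHA2 (limma, adjusted p = 1.34e-05, n = 21). CAV1, the main caveolin, rose by 2.09 ± 0.247 (adjusted p = 7.67e-05) and CAV2 by 1.19 ± 0.136 on its leading probe set (adjusted p = 7.67e-05). The cell cycle kinase CDK6 (slope 1.24), the transcription factor ETS1 (1.39), the urokinase gene PLAU (1.12), the growth factor PDGFC (1.03), and FRMD6, ELL2, PRNP, CRIM1 and FSTL1 (0.94 to 1.40) rose too. ELAPOR1 (−1.41), the sphingolipid enzyme DEGS2 (−1.21), the lipid transfer protein STARD10 (−1.48), the cholesterol transporter ABCG1 (−0.86) and the small GTPase RHOB (−1.17) fell, as did NR2F6, ICA1, LRIG1, GPD1L, NPDC1, HID1 and PRR14 (−0.81 to −0.56).

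**Figure D4:**
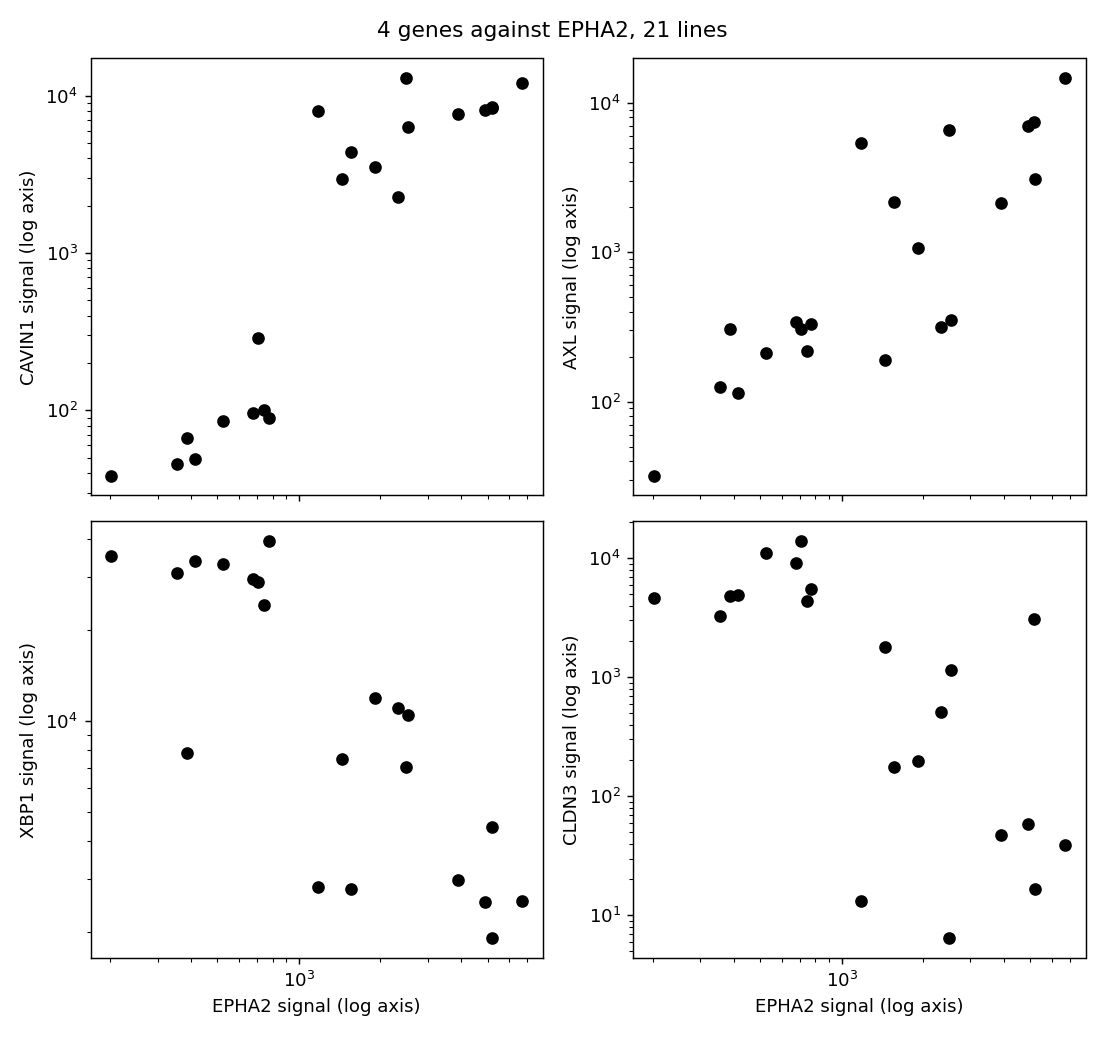
Signals of CAVIN1, AXL, XBP1 and CLDN3 against EPHA2 (log axes), 1 point for each of 21 lines. CAVIN1 and AXL rose with EPHA2 (slopes 1.76 and 1.25), and XBP1 and CLDN3 fell (−0.93 and −1.36).

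With EPHA2, of 14 luminal identity genes 8 fell, none rose and 6 did not pass, with 11 falling when adjusted over the list alone. They included the secretory pathway factor XBP1 (−0.93 ± 0.15, adjusted p = 0.000788), the pioneer factor FOXA1 (−0.99 ± 0.20, adjusted p = 0.00428) and GATA3 (−1.18 ± 0.25, adjusted p = 0.00744). The list's camera adjusted p was 3.04e-10 with a preset correlation and adjusted p = 0.0702 with an estimated correlation. Of 16 oestrogen receptor programme genes 7 fell and 9 did not pass (12 fell when adjusted over the list alone), among them CA12 (−1.31) and TFF1 (−1.61), with adjusted p = 0.0843 with an estimated correlation. Of 19 mesenchymal genes 9 rose and 10 did not pass (14 rose when adjusted over the list alone), led by the receptor kinase AXL (1.25 ± 0.19, adjusted p = 0.00058), TGFBI (1.33) and VIM (1.57), with adjusted p = 0.0843 with an estimated correlation. Of 18 epithelial junction genes the claudin CLDN3 (−1.36) and the protease PRSS8 (−0.76) fell and 16 did not pass (10 fell when adjusted over the list alone), with adjusted p = 0.339 with an estimated correlation.

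Of 15 focal adhesion genes 6 rose with EPHA2 (11 when adjusted over the list alone), including the integrins ITGA3 (0.50), ITGA5 (0.57) and ITGB1 (0.32), and the list's camera call held (adjusted p = 0.0115 with an estimated correlation). Of 14 interferon response genes 6 rose (8 when adjusted over the list alone), led by IFIT3 (0.87) and by the antigen processing genes PSMB9 (0.94) and TAP1 (0.45), with adjusted p = 0.0843 with an estimated correlation. Of 14 basal genes S100A2 (1.20), LAMB3 (0.93) and EGFR (1.20) rose, the same 3 when adjusted over the list alone (adjusted p = 0.339 with an estimated correlation). Of 10 dasatinib target kinases tested, LYN rose (0.64 ± 0.14, adjusted p = 0.00885) and 2 rose when adjusted over the list alone, and the list's call held (adjusted p = 0.0457 with an estimated correlation). The 5 published candidate markers other than EPHA2 all passed, CAV1, CAV2 (1.58 on its brightest probe set), CAVIN1 and ANXA1 (1.77) rising and IGFBP2 (−1.03) falling, over all genes and when adjusted over the list alone (adjusted p = 0.0283 with an estimated correlation). The marker list came from general knowledge of published work on breast cancer lines, which may include these, so this is not independent evidence of their direction.

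Receptor kinases went both ways with EPHA2. Of 16 tested, AXL, MET (1.16) and EGFR rose and ERBB3 (−1.05) and FGFR4 (−0.96) fell, 5 rising and 3 falling when adjusted over the list alone (camera adjusted p = 0.579, median slope −0.07, mean 0.07). Of the 18 proliferation genes CDC20 (0.41) rose, of 8p12 BAG4 (0.51) rose, of 20q13 BCAS1 (−0.58) fell, and of the unfolded protein response XBP1 fell. For 17q12, 17q23, 20q13 and proliferation, preset calls were lost, with adjusted p = 0.553, 0.474, 0.454 and 0.510 with an estimated correlation. The 11q13, MHC class II, tumour suppressor, melanocyte, leukocyte, fibroblast stroma, neuroendocrine and hypoxia lists held no gene that passed and no call.

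In all, 1946 of 30618 probe sets passed an adjusted p of 0.05 with EPHA2, 1160 rising (759 genes) and 786 falling (541 genes). MDA-MB-453, BT-474 and ZR-75-1, whose U133B arrays deviated, were among the lines of lowest EPHA2 (202, 353 and 413), and without them 390 passed, 344 of these among the 1946. The 24 genes named first all stayed, but of 50 list members that had passed, 19 stayed. With the luminal identity score as a term 3 passed (3044 at an unadjusted p under 0.05), with the epithelial junction clusters as a term 367, and with a term for the 2 sides of EPHA2's widest gap 947.

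ESR1 was followed as the main divide between breast cancers. GREB1, an oestrogen receptor cofactor, rose by 1.10 ± 0.114 (SE) per log2 unit of ESR1 (limma, adjusted p = 3e-05, n = 21), TFF1 by 1.46 ± 0.184 (adjusted p = 0.000237) and the survival gene BCL2 by 0.57 ± 0.064 (adjusted p = 5.97e-05). ABAT (0.91), DCPH1 (0.53), LONRF2 (0.71), ZFYVE21 (0.29), HEATR6 (0.55), the transcriptional repressor ZNF703 (0.78) and DEGS2 (0.80) rose too. The protease CTSC (−0.96 ± 0.147, adjusted p = 0.00189), CDK6 (−0.88), MARCKS (−0.73), FXYD5 (−0.78), B3GNT5 (−0.81) and the mitotic kinesin KIF2C (−0.23) fell, with BTG3, CCDC82, RND3, FIGN, OXR1 and PGM1 (−0.61 to −0.43).

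Of 15 other oestrogen receptor programme genes 6 rose, GREB1, BCL2, TFF1, PDZK1 (0.78), IGF1R (0.42) and MYB (0.47), and 13 rose when adjusted over the list alone. The list's camera call held (adjusted p = 4.16e-05 with an estimated correlation). The 17q23 list behaved alike: PPM1D (0.60), TRIM37 (0.48), BCAS3 (0.65) and RPS6KB1 (0.50) of its 7 genes rose, all 7 when adjusted over the list alone (adjusted p = 0.0191 with an estimated correlation). MCF7 and H3396, the lines of highest ESR1 among the 21, also had the highest 17q23 scores (2.26 and 1.95, with 0.728 in BT-474, the next). Both were counted as independent lines, although whether they are related was not tested. No fit left out both, so the 17q23 call may rest on them. Of 14 luminal identity genes PRLR (0.66), FOXA1 (0.71), GATA3 (0.83) and ERBB3 (0.76) rose, 10 when adjusted over the list alone (adjusted p = 0.0817 with an estimated correlation).

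Of the published candidate markers ANXA1 (−1.15), CAV1 (−1.17) and CAVIN1 (−0.92) fell and 3 did not pass, with 5 falling and 1 rising when adjusted over the list alone (adjusted p = 0.0817 with an estimated correlation), again not independent evidence. With a term for the sides of ESR1's widest gap the slope of CAV1 turned to 0.33 and that of CDC20 to 0.19, neither passing. No mesenchymal gene passed, and 4 of 19 fell when adjusted over the list alone. CLDN3 (0.88) of the junction list and ZNF217 (0.39) of 20q13 rose, CDC20 (−0.33) of the proliferation list fell, and IGF1R and ERBB3 were the receptor kinases that rose, with 4 rising and 5 falling when adjusted over the list alone. Preset calls were lost for epithelial junction, mesenchymal, 20q13 and proliferation (each adjusted p = 0.263 with an estimated correlation), basal genes (0.348), focal adhesion (0.168), interferon response (0.481) and hypoxia (0.298).

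With ESR1, 379 of 30613 probe sets passed, 219 rising (152 genes) and 160 falling (108 genes). The number depended on single lines: it was 107 without MCF7, 131 without H3396, 214 without HS578T, 215 without HCC1428, 227 without MDA-MB-231, 239 without ZR-75-1, 246 without HCC1419, 639 without SK-BR-3 and 1028 without MDA-MB-453. With a term for the 2 sides of ESR1's widest gap limma called 0 (2277 at an unadjusted p under 0.05), with the mean of the ESR1 probe sets 165, with the luminal identity score as a term 31, with the junction clusters as a term 52, with all 23 lines 697 and without the 3 lines of deviating U133B arrays 655.

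ERBB2 was followed within its clusters of 16 and 5 lines, so its slopes leave out the difference between the clusters and use the variation within both. CRB3, a polarity protein, rose by 1.06 ± 0.174 (SE) per log2 unit of ERBB2 (limma, adjusted p = 0.00422, n = 21), the receptor kinase FGFR4 by 1.62 ± 0.266 (adjusted p = 0.00572) and the epithelial transcription factor OVOL2 by 0.70 (adjusted p = 0.00895). FGFR4 read 34346 in MDA-MB-453, the highest of the 16 lower lines in ERBB2, with 4049 in the next line and a median of 245. That line may thus weigh heavily in the FGFR4 slope. HID1 (1.07), CRACR2B (1.44), CDS1 (1.15), ESPN (1.24), LIMK2 (0.67), GALNT6 (1.21), ZNF524 (0.80), FAM110A (0.88) and EPN3 (1.30) rose too. MACF1, a cytoskeletal linker, fell by 1.05 ± 0.123 (adjusted p = 0.00052). ERICH1 (−0.97), TNFAIP3 (−0.68), SGCB (−1.09), TWSG1 (−0.93), DOCK5 (−0.94), CEP41, ZCCHC7, SLC38A9, CMSS1, SFR1 and ERI1 (−0.88 to −0.70) also fell. Of these 24 genes, 6 passed without MDA-MB-453, BT-474 and ZR-75-1, whose U133B arrays deviated. Whichever single line was left out, 12 passed, and 0 passed with the luminal identity score or the junction clusters as a term. On U133A alone 8 of them were tested, and all 8 passed. The others were read on U133B, where the array of MDA-MB-453 deviated most.

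Of 18 epithelial junction genes 10 rose, among them SPINT1 (1.52 ± 0.29, adjusted p = 0.0111), PRSS8 (1.11), RAB25 (1.64) and EPCAM (1.58), and 17 rose when adjusted over the list alone (adjusted p = 0.179 with an estimated correlation). Of 14 luminal identity genes GATA3 (1.47), SPDEF (1.20), AGR2 (1.60) and TSPAN1 (1.12) rose, 10 when adjusted over the list alone (adjusted p = 0.179 with an estimated correlation). Of 19 mesenchymal genes FN1 (−1.46), ZEB1 (−0.97), TGFBI (−1.41) and VIM (−1.72) fell, 15 when adjusted over the list alone (adjusted p = 0.179 with an estimated correlation). Of the published candidate markers CAV1 (−1.90) and ANXA1 (−1.78) fell, with 5 falling and 1 rising when adjusted over the list alone (adjusted p = 0.246 with an estimated correlation), not independent evidence. VCL (−0.52) and LPP (−0.67) of the focal adhesion list and FAP (−0.77) of the fibroblast stroma list fell. Of 11 other 17q12 genes none passed over all genes and 4 rose when adjusted over the list alone (adjusted p = 0.246 with an estimated correlation). Of the 11 dasatinib target kinases none passed over all genes and 6 fell when adjusted over the list alone, with adjusted p = 0.179 with an estimated correlation, as for the melanocyte list. Focal adhesion had adjusted p = 0.246 with an estimated correlation.

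With ERBB2, 994 of 30616 probe sets passed, 420 rising (294 genes) and 574 falling (443 genes), so 42.3% rose, and with a pseudocount of 1 times the median 52.8% of 863 did. The share rising was 51.1% with no filter, 51.5% without the cluster term and 51.9% on U133A alone. The balance also turned without MDA-MB-453, where 130 rose and 60 fell (68.4% rising), and without it, BT-474 and ZR-75-1, where 59 rose and 15 fell (79.7%). The calls rested on MDA-MB-453, the highest of the 16 lower lines: 190 passed without it and 74 without it, BT-474 and ZR-75-1, of which 36 were among the 994. There were 412 without ZR-75-1, 508 without HS578T, 534 without MDA-MB-435S, 554 without MDA-MB-436, 559 without BT-549 and 640 without MDA-MB-231. Without the cluster term 390 passed, with the mean of the ERBB2 probe sets 518, and with the luminal identity score or the junction clusters as a further term limma called 0 (3284 and 3985 at an unadjusted p under 0.05).

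EPHA2 and ESR1 shared 169 probe sets of opposite direction and 0 of the same. EPHA2 and ERBB2 shared 392 of opposite direction and 0 of the same. ESR1 and ERBB2 shared 12 of the same direction and 0 of opposite direction. All 3 scans used the same arrays, so a relation between the index genes alone can set the direction of shared calls, and these numbers were not tested.

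In the comparison of the line labelled MCF7/Her2 with MCF7, ERBB2 itself was not higher. Its brightest probe set read 1542 in the line labelled MCF7/Her2 and 1752 in MCF7 (a log2 difference of −0.17), both below the median of the 21 lines. The second U133A probe set read 112 and 537, and the one on U133B 126 and 99.5, where SK-BR-3 read 12725 and 3760. A transcript without the region these probe sets read would not be seen. The difference between these lines has no replicate check.

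S100P, a calcium-binding protein, read 14828 in the line labelled MCF7/Her2 and 40.1 in MCF7 (log2 difference 6.47). WDR72 (6.03), HMCN1 (5.42), the growth factor binding protein IGFBP5 (5.40), MARCKS (5.38), AGR3 (4.85), FAM133A (4.66), MAN1A1 (4.59), the receptor kinase ERBB4 (4.49) and the adhesion molecule CEACAM6 (4.41) were also higher. PI15 read 81.5 and 78544 (−8.21), and the neuropeptide receptor NPY1R (−7.33), FHL2 (−5.80), the oestrogen target PDZK1 (−5.58), MGP (−5.20), CRISPLD1 (−4.64), EPHA4 (−4.58), ARHGAP36, AMIGO2 and GDAP1 (−4.53 to −4.49) were lower. These differences are on the log2(signal + pseudocount) scale, which understates the change of low genes. Of other probe sets of the same gene that reached the array median, 1 of 3 for IGFBP5 and 4 of 4 for MARCKS were at least 2-fold higher.

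Of 25047 probe sets compared, 319 were at least 4-fold higher and 320 at least 4-fold lower in the line labelled MCF7/Her2. The list medians were high for the interferon response (0.68, the 99.96 percentile of 10000 random lists), luminal identity (0.35, 99), and the unfolded protein response (0.43, 97.95), with MUC1 (3.79), AGR2 (2.99), SPDEF (2.52) and TSPAN1 (2.15) among the luminal genes. They were low for mesenchymal genes (−0.67, 0.07), 11q13 (−0.59, 1.71) and the oestrogen receptor programme (−0.33, 2.18), where BCL2 (−2.06) was 4-fold lower. Single list members 4-fold higher elsewhere were FGFR4 (2.46), ITGB4 (2.18), TYRP1 (2.42) and MITF (2.09), and IFI44 (−2.05) was 4-fold lower within the interferon list. With a pseudocount of 0.05 times the median 656 were higher and 631 lower, and with 1 times the median 98 and 86.

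AU-565 and SK-BR-3 are sister lines with no named change between them. Each was read on 1 array per design, so differences of the cells could not be told apart from differences of the arrays. The lipid enzyme ACSL5 read 22080 in AU-565 and 409 in SK-BR-3 (log2 difference 5.23). CRISP3 (4.80), VCX2 (4.63), the scavenger receptor gene CD163L1 (4.40), the fibrinogen chain FGG (4.35), AZGP1 (4.26), the mammaglobin gene SCGB2A2 (4.24), ADRB1 (4.22), VSIG10L and PLEKHH1 (both 4.17) were higher. The amyloid precursor protease BACE1 (−3.69), PITRM1 (−3.62), ZMIZ2 (−3.42), LOC102723692, KCNMA1, ELOVL7, LINC00674, NRSN1, SCP2D1-AS1 and VANGL2 (−3.31 to −3.02) were lower. The other ADRB1 probe set that reached the array median did not share the direction, and for ZMIZ2 1 of 2 did. For PITRM1 and KCNMA1 the other such probe set was lower too, but not by 2-fold. Of list members, CRYAB (2.88), MUC1 (2.86), TOX3 (2.84) and EGLN3 (2.40) were 4-fold higher and FGFR3 (−2.78), GATA3 (−2.31) and TFF1 (−2.05) 4-fold lower.

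Of 25259 probe sets 281 were at least 4-fold higher and 378 at least 4-fold lower in AU-565. Proliferation genes had a median of −0.58, the 0.01 percentile of random lists, and 20q13 −0.43 (1.99). Basal genes had 0.40 (99.61) and the published candidate markers 0.77 (99.34). Of the changed probe sets 507 lay on U133B and 152 on U133A, and the differences of the shared probe sets on both designs correlated with r = 0.508 (across probe sets, which are not independent replicates), against 344, 295 and r = 0.747 in the MCF7 pair. With a pseudocount of 0.05 times the median 597 were higher and 795 lower, and with 1 times the median 60 and 19. The median signal on U133B was 704.5 in AU-565 and 821.2 in SK-BR-3, and on U133A 506.9 and 508.2. How much of the difference comes from the U133B arrays was not tested.

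Among the 253 pairs of lines, AU-565 and SK-BR-3 were the nearest (r = 0.478 over centred probe sets, the median pair having −0.0814). The line labelled MCF7/Her2 came next, at 0.443 with H3396 and 0.438 with MCF7. HS578T and BT-549 followed with 0.432, and H3396 and MCF7 with 0.379. These r describe distances across probe sets, which are not independent replicates.

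Some probe sets read far higher in 1 line than in any unrelated line. SK-BR-3 and AU-565 were not compared with each other here, nor were MCF7 and the line labelled MCF7/Her2. The gap of MSL1 in SK-BR-3 thus says nothing of its level in AU-565. By a gap of at least 8-fold over the next unrelated line there were 105, 82 with a gene name, 73 on U133A and 32 on U133B. MDA-MB-435S held 23, led among those with a gene name by the calcium-binding protein S100B (4951, next 60.9) and HLA-DRA (33621, next 1751). HS578T held 11, led by the receptor kinase PDGFRA (11831, next 239) and the sodium channel SCN3A (3989, next 117). HCC70 had the protease inhibitors SERPINB3 (7783) and SERPINB4 (7613), BT-549 the chemokines CXCL5 (10530) and CXCL1 (40694), and HCC1428 the chemokine CXCL14 (96508) and ZDHHC22 (5905). MDA-MB-468 had the psoriasin gene S100A7 (38107), BT-20 OLFM4 (11516) and the oestrogen-making enzyme HSD17B1 (21262), and MDA-MB-453 the transporter SLC1A7 (53491) and CLCA2 (28888). MCF7 had PI15 (78544) and NPY1R (29527), and HCC1419 the adrenaline-making enzyme PNMT, a 17q12 gene (19542), and FCGRT (8973). MDA-MB-436 had C1QTNF4 (11588) and AQP9 (4363), MDA-MB-231 ADGRF5 (5172) and C4BPB (2918), and HCC38 PCDHB5 (13774) and HOXB-AS3 (8062). BT-474 had KIF1A (23192) and IKZF3 (10932), HCC1806 LVRN (13173) and GJB6 (3521), and ZR-75-30 CLEC3A (44623) and BPIFB2 (15269). All 3 probe sets of BT-474, and the SLC1A7 probe set named for MDA-MB-453, were read on U133B. The U133B arrays of these lines deviated, so the values carry a larger error. A U133A probe set of SLC1A7 also passed in MDA-MB-453 (11404, next 382.5). SK-BR-3 had MSL1 (22821), AU-565 FGG (5814) and HCC1954 GSDMB (3959). The gap does not mean absence elsewhere: MSL1 had a median of 1758, CLEC3A of 1461, and PI15 read 5491 and CXCL14 4161 in the next line. It also holds for the probe set alone, since the brightest GSDMB probe set read 21889 in AU-565, 20715 in SK-BR-3 and 7786 in HCC1954. MDA-MB-157, H3396, ZR-75-1 and the line labelled MCF7/Her2 had none. With a pseudocount of 1 times the median 48 probe sets were found.

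The 100 probe sets carried by both designs gave the only repeat measurement. After removal of each probe set's mean difference, the SD of the log2 difference between a line's arrays had a median of 0.241 over the 23 lines. It lay between 0.145 and 0.310 in 20 lines, and was 1.07 in MDA-MB-453, 0.810 in BT-474 and 0.590 in ZR-75-1. By correlation of these probe sets, 22 of the 23 U133A arrays matched their own U133B array best. The exception was MDA-MB-453, whose U133A array had r = 0.435 with the U133B array of HCC1419 and 0.0901 with its own, across probe sets, which are not independent replicates.

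**Figure D5:**
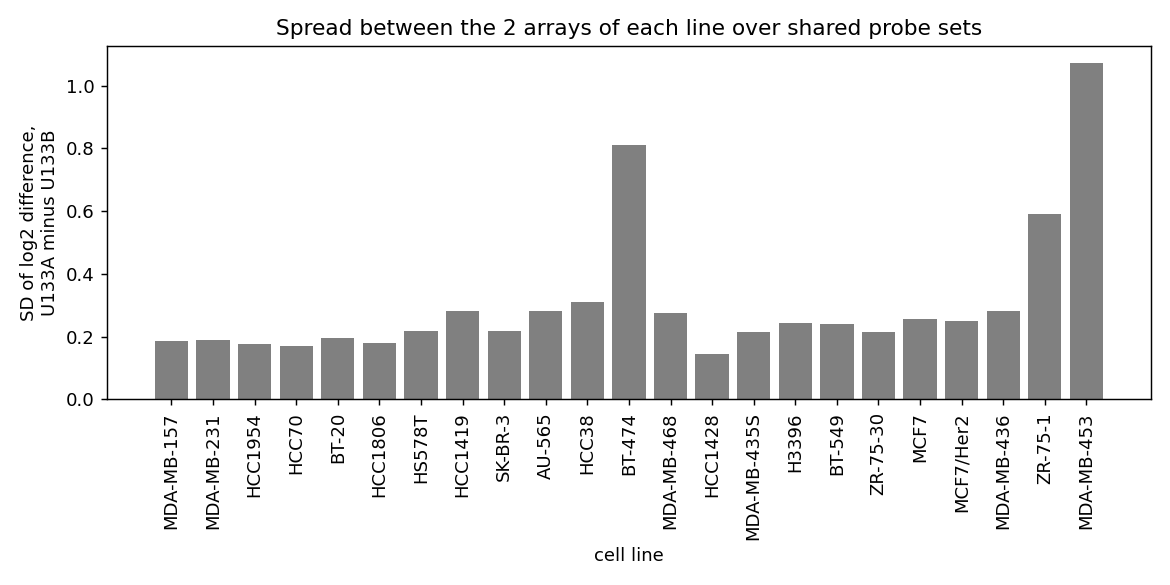
SD of the log2 difference between the U133A and U133B array of each line over 100 shared probe sets (bars, 1 per line). MDA-MB-453 (1.07), BT-474 (0.810) and ZR-75-1 (0.590) lay above the other lines, which reached at most 0.310.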

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

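The alternatives with U133A arrays alone, without MDA-MB-453, BT-474 and ZR-75-1, and with a luminal identity or junction term were chosen after the results had been seen. Where a count fell with fewer lines or arrays, or a call was lost with fewer lines, the alternative's own construction may account for part of it. Having fewer lines does not account in this way for counts that rose or calls that were gained. Otherwise the cause of a change was not tested. Signals near the pseudocount limit what low probe sets can show.

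The number of probe sets called with EPHA2 was 1946. It was 947 with a term for the sides of its widest gap, 1242 on U133A alone, 390 without the 3 lines, 3 with the luminal term and 367 with the junction term, and ran from 1312 (without BT-474) to 2163 (without MDA-MB-435S) with each line left out. With ESR1 it was 379, and 697 with all 23 lines, 165 with the mean of the probe sets, 0 with the cluster term (limma, 2277 at an unadjusted p under 0.05), 655 without the 3 lines, 31 with the luminal term and 52 with the junction term, and ran from 107 (without MCF7) to 1028 (without MDA-MB-453). With ERBB2 it was 994, and 534 without MDA-MB-435S, 518 with the mean of the probe sets, 390 without the cluster term, 293 on U133A alone, 74 without the 3 lines and 0 with the luminal or the junction term (limma, 3284 and 3985 at an unadjusted p under 0.05), and ran from 190 (without MDA-MB-453) to 1406 (without BT-20). Counts under the other alternatives, apart from single lines left out, stayed within 1.5 times.

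Of the 24 genes named first with EPHA2, 2 passed with the luminal term, 23 with the term for its gap, and all 24 without the 3 lines. Of 50 list members 0 passed with the luminal term, 14 with the junction term, 19 with the term for its gap and 19 without the 3 lines. Of the 24 named first with ESR1, 0 passed with the cluster term, 10 with the luminal term and 17 with the junction term, and of 15 list members 0, 4 and 4, and 7 with the mean of the probe sets. Of the 24 named first with ERBB2, 7 passed without the cluster term, 6 without the 3 lines and 0 with the luminal or junction term, and of 22 list members 6, 5 and 0, and 6 without MDA-MB-435S. Whichever single line was left out, 33 of the 50 list members with EPHA2 passed, 3 of the 15 with ESR1 and 3 of the 22 with ERBB2, and of the 24 named first 24, 23 and 12. PRSS8 reversed with EPHA2 under the luminal term (0.10), and CAV1 (0.33) and CDC20 (0.19) reversed with ESR1 under the cluster term.

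Proliferation with luminal identity gave r = −0.575 with the lower pseudocount, −0.564 without MDA-MB-435S and −0.606 without the 3 lines, each past the threshold no longer, and −0.640 (without HS578T) to −0.499 (without ZR-75-30) with each line left out. Proliferation with the oestrogen receptor programme in the lower lines gave r = −0.704 with the lower pseudocount, −0.660 with the mean of the probe sets, −0.618 with all 23 lines, −0.741 without MDA-MB-435S and −0.740 without the 3 lines, none past the threshold, and −0.784 (without HCC70) to −0.407 (without ZR-75-30). Interferon response with luminal identity ran from −0.664 (without HS578T, past the threshold) to −0.500 (without ZR-75-30). Of 246 alternative values of relations 235 kept direction and side of the threshold, as did 250 of 260 mean pairwise r values.

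The mean pairwise r of neuroendocrine markers passed the threshold with the lower pseudocount (0.164) and without the 3 lines (0.176), and ran from 0.130 (without MDA-MB-231) to 0.198 (without BT-549). That of the unfolded protein response passed with the higher pseudocount (0.111), quantile normalization (0.110), all 23 lines (0.126) and without the 3 lines (0.103), and ran from 0.0953 (without BT-474) to 0.132 (without H3396). The oestrogen receptor programme's lower lines ran from 0.0131 (without ZR-75-30) to 0.112 (without MDA-MB-453), and the junction list's higher lines from 0.0561 (without HCC1806) to 0.123 (without SK-BR-3).

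The probe sets changed between the line labelled MCF7/Her2 and MCF7 numbered 639, and 1287, 184 and 359 with the lower and higher pseudocount and the 75th percentile filter. Between AU-565 and SK-BR-3 they numbered 659, and 1392, 79 and 285. The line labelled MCF7/Her2 and MCF7 ranked 3 among pairs by distance, and 4 with the lower pseudocount and with no filter. Probe sets with an 8-fold gap between 1 line and the next unrelated line fell from 105 to 48 with the higher pseudocount. Of 58 differences named in the pairs, 48 moved with the lower and 56 with the higher pseudocount by more than the spread between designs. A pseudocount added to both signals cannot turn a direction, so these settings do not test it. With quantile normalization 1 of the 58 moved and 0 turned.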

Other observations

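The tests of other orders of the index values, of matching arrays, of RNA quality, of exchanged labels, of another line's array and of the ERBB2 probe sets were chosen after the results had been seen. The tests of the U133A arrays alone, of other sets of 3 lines and of bright probe sets were set down before theirs.

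MDA-MB-435S expressed genes of pigment cells and of antigen presentation that no other line had at such levels. Its melanocyte score was 2.66, with 0.237 in the next line, MDA-MB-231. SOX10, a neural crest transcription factor, read 8446 with 369 in the next line. MITF, the master regulator of melanocytes, read 13995 against a median of 2137. TYR, the first enzyme of melanin synthesis, read 2424 with 551 in the next line. The endothelin receptor EDNRB read 3749, with 916 in the next line, MDA-MB-231, and a median of 188. MLANA read 779 and PMEL 571, and PMEL was higher in BT-20 (707), H3396 (644) and AU-565 (632). The MHC class II score was 3.14, with 1.19 in BT-20. HLA-DRA read 31605 and the invariant chain CD74 23567, against medians of 153 and 266, while their activator CIITA read 797, with 761 in BT-20. HS578T led the fibroblast stroma score (2.82, with 1.57 in MDA-MB-157), with COL1A1 at 53589 and DCN at 9978.

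Several tumour suppressor genes were near the floor in single lines. RB1 read 3.5 in MDA-MB-468, 53.5 in BT-549 and 134 in MDA-MB-436, against a median of 1362. MTAP, a 9p21 neighbour of CDKN2A, read 47.1 in MDA-MB-231, 111 in H3396, 118 in HCC38, 136 in the line labelled MCF7/Her2, 159 in MCF7 and 230 in BT-474, against 1932. CDH1, the epithelial cadherin, read 24.6 in SK-BR-3 and 202 in AU-565, whose junction scores, with CDH1 among the members, were 0.584 and 0.620, and 7.7 to 47.8 in MDA-MB-436, HS578T, MDA-MB-157, MDA-MB-231 and BT-549, against 6151. MTAP was read on U133B, where the array of BT-474 deviated, so its value there is uncertain. Hypoxia genes scored highest in BT-474 (1.21) and HS578T (1.12), where the vasodilator gene ADM read 19108 against 1522. EGFR read 86371 in MDA-MB-468 and 24.6 in HCC1419, and FGFR4 34346 in MDA-MB-453 against 245.

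Chance orders of the lines did not give the numbers of genes that vary with the index genes. With 100 orders of the EPHA2 values over the lines, the real one included, 1 called as many as 1946 probe sets, the highest of the others calling 3. With ESR1 it was 1 of 100 (379, highest other 12), and with ERBB2, reordered within its clusters, 1 of 100 (994, highest other 261). No other order drawn gave these 3 numbers, but 100 orders, in a test chosen after the results, do not exclude chance. For ERBB2 a chance order called 261, more than the real order without MDA-MB-453 (190) or without it, BT-474 and ZR-75-1 (74), though with fewer lines. The orders also say nothing of what EPHA2 in particular adds, since 3 calls stayed with the luminal identity score as a term.

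Without MDA-MB-453, BT-474 and ZR-75-1 the calls with EPHA2 fell from 1946 to 390. If the deviating U133B arrays were the whole cause, a scan of U133A arrays would have kept most calls, but it called 340 where it had called 1242, so at most 27.4% can have stayed, and at most 18.8% on U133B. Leaving out lines as such was argued against too, since 1 of 100 sets of 3 lines, these included, gave as few, the lowest of the others giving 511. What stays open is that these lines lay at the low end of EPHA2, which was not tested apart from their other properties, and no biological explanation was tested.

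The U133B arrays of MDA-MB-453, BT-474 and ZR-75-1 may have been of lower quality, for a cause that stays open, and had the highest share of signal in the 10 brightest probe sets (7.41%, 9.02% and 7.42%, with at most 6.38% in the others). An array of another line of the series was argued against for BT-474 and ZR-75-1, since over 1157 genes on both designs each U133B array matched its own U133A array best in 100% of 1000 gene resamples. For MDA-MB-453 it stays open: its U133B array matched its own U133A array best in 99% (r = 0.189, with 0.107 for the best other line), but that U133A array had a higher r with the U133B array of HCC1419 (0.269). Bright probe sets reading too low was tested by the slope of U133A minus U133B on U133A, which lay above the other 20 lines in 0 of 3. The slope argues against it for BT-474 (−0.161) and ZR-75-1 (−0.127), which lay below the other lines (−0.0505 to 0.0403). That departure the other way was not explained. For MDA-MB-453 bright probe sets reading too low stays open, since a slope cannot see a shift shared by all these probe sets. Its mean log2 difference, U133A minus U133B, relative to all lines was 1.13, with 0.354 in the next line, MDA-MB-468. Degraded RNA stayed open: 0 of 3 had ACTB and GAPDH 3' to 5' ratios on U133B both above the other 20. ACTB was low (0.172, 0.489 and 0.521, with 0.867 to 1.19 in the others), opposite to what degradation predicted. GAPDH was high in MDA-MB-453 and ZR-75-1 (2.42 and 1.15, with 0.876 to 1.08) but not in BT-474 (1.04). On U133A their GAPDH ratios (0.844, 0.795 and 0.837) lay within the range of the 23 lines (0.731 to 0.961). ACTB there was 1.24, the highest of all lines, 0.966 and 1.06. These bear on the U133B arrays only if both arrays used the same RNA. Neither a biological explanation nor a line outside the series was tested.

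ERBB2 was not higher in the line labelled MCF7/Her2 than in MCF7. An exchange of these labels was argued against on the brightest ERBB2 probe set alone, where MCF7 read 1752, below the median of 2326. A dimmer probe set, at 12725 in SK-BR-3, went the way an exchange predicts. It read 537 in MCF7, above its median of 378, and 112 in the line labelled MCF7/Her2. Whether the array came from another line cannot be told apart from a derivative that has drifted, since MCF7 was its nearest line in 27% of resamples of the probe sets and H3396 in 73%, while across designs its best match among the other lines was MCF7 over the shared probe sets (r = 0.344 and 0.355), and BCAS3 read 27938 in it, 28000 in MCF7 and 10257 in H3396. A transgene transcript outside the parts that the probe sets read could also leave ERBB2 unchanged, and 0 of 3 ERBB2 probe sets were 2-fold higher, which that explanation shares with a line that does not express the transgene. A biological difference between the lines stays open, as untested.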
